A study of Arabidopsis thaliana with 12 samples.

How the data were processed

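Total RNA from Arabidopsis thaliana seedlings was measured on 12 Affymetrix ATH1 arrays, 3 in each of 4 groups: wild type (WT, accession Col-0) and a line made to overexpress the transcription factor WRKY46 (46T), each untreated (control) or dehydrated. Per the labels' protocols, seedlings were 1 week old, were grown in 16 h of light at 24 °C and 8 h of dark at 21 °C, and the treated ones were laid on filter paper for 1 h at 22 °C and 60% humidity in dim light. RNA was labelled with biotin through a 3' in vitro transcription kit, per the labels' protocols. The labels call the 3 arrays of a group biological replicates, and each sample was placed in its group by its title. The number of arrays limits the precision.

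The deposited table gives 1 value per probe set and array, for 22810 probe sets. The signals were made with MAS5, per the submitters' processing notes, and its version is not given in the sources used here. The values deposited by the authors are log2 signals: raised back to the linear scale, their mean after trimming 2% at each end was between 500.0 and 500.1 on every array. No log2 value was below 0, with 169 to 394 values at 0 on each array. The table was taken as already normalized and was not normalized again. A MAS5 signal is the difference between matched and mismatched probes, so low signals vary more than high ones on the log2 scale, and folds of genes with a low signal in 1 group are uncertain.

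The 64 control probe sets were left out of the tests. Of the other 22746 probe sets, those above their array's 40th percentile on at least 3 of the 12 arrays were tested, 14495 in all. Each probe set was fitted with 4 group means in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), so that all groups shared 1 estimate of the spread. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested probe sets, and a probe set with an adjusted p below 0.05 was called. Errors of log2 differences are the standard errors (SE) of this fit, and errors of group levels are SD with n = 3. All adjusted p-values of single genes come from limma. The 5 comparisons were dehydration in WT, dehydration in 46T, 46T against WT in control seedlings, 46T against WT in dehydrated seedlings, and the interaction of line and dehydration.

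Probe sets were named through the platform annotation supplied with the table, with symbols updated through NCBI RefSeq's gene table for assembly TAIR10.1. This annotation lists 13513 probe sets with 1 gene, of which 13436 matched the RefSeq table, and 503 with several genes. The remaining 8794 are unnamed here. Of the tested probe sets, 7834 name 1 gene, 302 name several and 6359 are unnamed. A locus tag stands for a gene without a symbol. The annotation names no probe set for WRKY46, so its level is not analysed here and the overexpression stated in the labels was not checked.

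Named genes were chosen by a rule fixed before the data were examined: up to 8 genes with the largest rise and 8 with the largest fall among called probe sets naming 1 gene, with no overlap between the values of both groups and a higher mean at or above the median of all tested values. Where fewer than 5 genes passed, the 5 with the smallest p were taken and are said not to have passed. The rule adds up to 4 called members of each of 22 gene lists, or up to 2 with the smallest p where none passed. WRKY46 was named in it as well. The lists held 373 entries on dehydration, abscisic acid, defence, growth and other themes, of which 35 have a named probe set and 25 were tested, in 14 lists. The other 8 lists (abscisic acid metabolism, its receptors, clade A protein phosphatases, its kinases and transcription factors, osmolytes, jasmonate, aquaporins and heat shock) had no tested member. Lists with at least 5 tested genes were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. Only the auxin and growth list was large enough. Its camera p, called adjusted below, had no other list to be adjusted over and so equals the unadjusted p. Because so few list members were named, 33 further groups were formed after seeing this, but before their values were seen, from genes that share the letters opening their symbol, plus the plastid-encoded genes. Their members, and other genes said to lie outside the rule, were picked for the text after their values were seen.

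The pipeline was tested on simulated data with 100 probe sets of the 14495 changed 2-fold and 100 changed 4-fold. Of the 2-fold changes it recovered 79% for dehydration in WT, 78% for dehydration in 46T, 81% for the lines in control seedlings, 72% for the lines in dehydrated seedlings and 35% for the interaction. Of the 4-fold changes it recovered 98%, 100.0%, 98%, 100.0% and 94% in the same order. The changed probe sets were drawn from those with a mean signal at or above the median. Each probe set had the same simulated spread on every array. The real arrays were less even, with estimated array weights from 0.14 to 3.84, so these rates may be too high for them. In a separate run, 4 of 100 gene lists with no effect had a camera p below 0.05. Its probe sets were drawn independently of each other. It therefore cannot show how often the preset correlation gives false calls where the genes of a set vary together. Alternatives tried were quantile normalization, median centring, no filter, a stricter filter at the 60th percentile, a floor at the 25th percentile, a pseudocount of 32, no intensity trend, array weights, a fit of only the 2 groups compared, the replicate number as a block, a 2-fold minimum and leaving out each array in turn. The level of the poly-A labelling controls as a model term, fits without WT control replicate 1 in every comparison, leaving out each array in the tests of lists and families, and the contrast of the lines averaged over both conditions were added after seeing the data. A check against gene length was also run after seeing the data and then withdrawn, because the gene table serves here only for names and neighbours and because 28 of the 60 probe sets called between the lines had no length. Its outcome was mixed: the differences between the lines and the deviation of WT control replicate 1 followed gene length, while a correction for length left most of the difference of the called named genes, QQS among them, and of the plastid-encoded and auxin and growth sets, and decided nothing for the CML and LSM genes. Its values are not used here, for or against any result.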

Results

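The arrays compared gene expression in WT seedlings and in the WRKY46-overexpressing line 46T, with and without 1 h of dehydration, so that the response to dehydration, the difference between the lines and the dependence of one on the other could each be measured in 3 arrays per group. WRKY46 is a transcription factor of the WRKY group III, and the series title names osmotic stress responses and stomatal movement as its subject. Within a group, Spearman correlations of the tested probe sets ranged from 0.910 to 0.988. The first principal component held 43.3% of the variance and separated dehydrated from control arrays. The second held 27.2%, and on it WT control replicate 1 stood apart at 72.7, the other WT arrays lay between -20.1 and 29.3, and the 46T arrays lay between -25.0 and -13.8.

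The first comparison asked what 1 h of dehydration changed in WT seedlings. PUB19, a U-box E3 ubiquitin ligase, rose from a log2 signal of 4.30 ± 0.60 to 11.59 ± 0.49 (SD, n = 3 arrays per group), a log2 difference of 7.29 ± 0.28 (SE; limma adjusted p = 5.4e-09), or 5.89 with the pseudocount, since its control level is low. WRKY53, a transcription factor of the same group as WRKY46, rose by 5.21 ± 0.27 (adjusted p = 5.2e-08; 4.39 with the pseudocount), from 5.36 ± 0.61 to 10.57 ± 0.10 (SD, n = 3; limma). STZ, a zinc finger transcription factor of abiotic stress also called ZAT10, rose by 3.93 ± 0.36. The other large rises in WT were AT4G27657 (4.48 ± 0.24), AT4G29780 (4.13 ± 0.22), AT1G20823 (3.86 ± 0.31), AT2G22880 (3.77 ± 0.60) and AT3G10930 (3.62 ± 0.28).

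The falls in WT were smaller. AT5G02540 fell by 2.14 ± 0.25 on the log2 scale, AT3G62550 fell by 1.65 ± 0.28, AT5G25840 fell by 1.62 ± 0.24 and AT5G61590 fell by 1.54 ± 0.21. AT3G62820, AT2G15960, AT2G42040 and AT2G14900 fell by 1.43 to 1.29. Without WT dehydrated replicate 1, AT2G15960, AT2G42040, CML37 and GRX480 lost their calls, and without WT dehydrated replicate 2, AT2G15960 and AT2G14900 did. Among the fixed lists, both tested genes of the touch and calcium list rose, the calmodulin-like calcium sensors CML37 (3.14 ± 0.69; 1.94 with the floor and 1.60 with the pseudocount) and CML38 (2.41 ± 0.31). The touch list was included as a check on handling, so these rises cannot be credited to water loss alone. Of the 2 tested genes for redox and detoxification, the glutaredoxin GRX480 rose by 1.55 ± 0.33. STZ was the only tested stress transcription factor and WRKY53 the only tested WRKY group III gene. Over the 24 tested list genes apart from reference genes, 5 rose, 0 fell and 19 did not pass. With p adjusted over the list alone, 5 of these 24 rose and 1 fell. Here and below, that adjustment took all 25 tested list genes as 1 list, the reference gene included. None of the 5 auxin and growth genes passed (median -0.32, camera adjusted p = 0.142), although IAA29 (-1.43) did in 4 of 17 alternatives and LBD16 (-0.81) in 1 of 16.

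Of the 8 tested PUB genes, 6 rose in WT: PUB19, PUB23 (2.73 ± 0.30), PUB24 (2.39 ± 0.19), PUB22 (1.56 ± 0.25), PUB26 (1.22 ± 0.22) and PUB25 (0.91 ± 0.16). The family's median was 1.39 (camera adjusted p = 1.1e-06; adjusted p = 0.0148 with an estimated correlation). WRKY53 and WRKY6 (1.79 ± 0.27) were the 2 of 5 tested WRKY genes that rose, with a family median of 0.42 (camera adjusted p = 0.00148; adjusted p = 0.0974 with an estimated correlation). Of 8 tested ATG genes, 7 of which encode ATG8, the ubiquitin-like protein of the autophagosome, 3 fell: ATG8F fell by 0.95 ± 0.17, ATG8E fell by 0.84 ± 0.21 and ATG8C fell by 0.77 ± 0.21. Without any 1 of the WT dehydrated replicates, ATG8E and ATG8C lost their calls, and with array weights their falls were 0.53 and 0.45. Without WT control replicate 1 the fall of ATG8C was 0.50. The family's median was -0.47 (camera adjusted p = 0.00184; adjusted p = 0.616 with an estimated correlation). Of 7 tested CML genes 4 rose, CML37, CML38, CML23 (1.47 ± 0.30) and CML42 (0.62 ± 0.16). CML42 was not called without WT control replicate 3, WT dehydrated replicate 1 or WT dehydrated replicate 2. The CML family did not pass (camera adjusted p = 0.0708; 0.0142 without WT control replicate 1 and 0.0411 without WT dehydrated replicate 3). The 67 plastid-encoded genes passed at the preset correlation (median 0.27, adjusted p = 0.0272). They did not pass without WT control replicate 2 (median 0.05, adjusted p = 0.970) or WT dehydrated replicate 1 (median 0.15, adjusted p = 0.271). The median was 0.17 without WT control replicate 1 and 0.47 without WT control replicate 3. The 2 called members, psbI (-0.78 ± 0.19; -0.50 with array weights; not called without WT dehydrated replicate 2 or 3) and psbK (-0.87 ± 0.19), fell, against the median. The family's adjusted p was 0.998 with an estimated correlation.

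In all, 1680 of 14495 probe sets were called in WT, 1057 higher and 623 lower after dehydration, and 701 of them differed at least 2-fold. The count was 833 without WT dehydrated replicate 1 (623 higher, 210 lower), 869 without WT dehydrated replicate 2 (649 higher, 220 lower), and 2372 without WT control replicate 1 (1221 higher, 1151 lower). It was 3469 with array weights (1759 higher, 1710 lower) and 751 in a fit of these groups alone (607 higher, 144 lower).

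The same treatment was then compared within 46T. AT2G22880 rose by 6.69 ± 0.60 (limma adjusted p = 3.7e-06), or by 4.38 with the floor and less than that with the pseudocount, PUB19 by 6.22 ± 0.28 (adjusted p = 9.3e-09; 5.34 with the pseudocount) and WRKY53 by 5.28 ± 0.27 (adjusted p = 2.7e-08; 4.49 with the pseudocount). The other large rises were AT3G02840 (5.04 ± 0.57), AT5G64870 (5.03 ± 0.42; 3.33 with the pseudocount), STZ (4.72 ± 0.36), AT4G27657 (4.59 ± 0.24) and AT4G29780 (4.52 ± 0.22). Of the falls, AT1G19530 had the largest, the plant defensin gene PDF1.4 fell by 2.23 ± 0.64, AT5G25840 fell by 2.03 ± 0.24 and AT4G10910 fell by 2.03 ± 0.26. AT3G62820, AT3G62550, CCL and AT1G33811 fell by 1.95 to 1.42. PDF1.4 lost its call in 7 of 17 alternatives, among them leaving out any 46T array but dehydrated replicate 3, and its fall was 1.34 without 46T dehydrated replicate 2.

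Among the lists in 46T, CML37 rose by 4.54 ± 0.69 (2.47 with the pseudocount) and CML38 by 4.28 ± 0.31. COR47, a dehydrin gene, rose by 1.11 ± 0.23 and was the 1 called gene of 3 tested in the dehydration and abscisic acid list. FMA, also called FAMA, a transcription factor of guard cell formation, was the 1 tested guard cell gene. It fell by 1.37 ± 0.31, a call lost without 46T control replicate 1 or 46T dehydrated replicate 1. In WT, 0 of the 3 dehydration and abscisic acid genes were called, though all 3 differences were positive (median 0.65). FMA changed by -0.41 in WT and was not called. The interaction called neither COR47 nor FMA, so these calls do not set 46T apart from WT. Over the 24 list genes, 5 rose, 1 fell and 18 did not pass, and with p adjusted over the list alone 9 rose and 2 fell. The median of the auxin and growth list was -0.05 (camera adjusted p = 0.441), or 0.37 without 46T dehydrated replicate 1 (adjusted p = 0.0215). Of the PUB genes, 6 of 8 rose again (median 1.36, camera adjusted p = 1.9e-07; adjusted p = 0.0103 with an estimated correlation), among them PUB23 (2.46 ± 0.30) and PUB24 (2.23 ± 0.19). PUB25 lost its call without 46T control replicate 2, and PUB26 without that array, 46T control replicate 3 or 46T dehydrated replicate 1. The same 4 of 7 CML genes rose as in WT, the list genes and also CML23 (2.44 ± 0.30) and CML42 (1.01 ± 0.16), with a median of 1.01 (camera adjusted p = 9.9e-05; adjusted p = 0.122 with an estimated correlation). WRKY53, WRKY6 (1.64 ± 0.27) and WRKY22 (0.84 ± 0.20) rose among 5 WRKY genes (camera adjusted p = 1.9e-04; adjusted p = 0.0582 with an estimated correlation). WRKY22 lost its call without 46T control replicate 1, 46T control replicate 3 or 46T dehydrated replicate 3. Of the ATG genes, ATG8B fell by 0.53 ± 0.16 (family median -0.49, camera adjusted p = 0.0455; adjusted p = 0.802 with an estimated correlation), a call lost in 9 of 17 alternatives, among them leaving out any 46T array. The family's call was lost without 46T control replicates 1 or 3 or 46T dehydrated replicate 1. The GH genes, which pool GH3 and GH9 members by their opening letters and are not 1 gene family, also passed at the preset correlation (median 0.25). They did not pass without WT control replicate 1, 46T control replicate 2 (median 0.10) or 46T dehydrated replicate 3. Their median was 0.39 without 46T control replicate 3 and 0.12 without 46T dehydrated replicate 1, and their adjusted p was 0.358 with an estimated correlation.

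In 46T, 1476 probe sets were called, 969 higher and 507 lower, and 733 differed at least 2-fold. The count was 772 without 46T dehydrated replicate 1, 879 without 46T control replicate 2 and 834 without 46T control replicate 3. It was 3770 with array weights (1795 higher, 1975 lower) and 3079 in a fit of these groups alone (1476 higher, 1603 lower), so that the excess of rises does not hold there. It was 2382 (1268 higher, 1114 lower) when WT control replicate 1, which is not part of this comparison, was left out of the shared spread.

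Across the 14495 probe sets, the dehydration responses of both lines, which share no arrays, correlated with Pearson's r = 0.85 and Spearman's rho = 0.72, and the slope of 46T on WT was 0.89. Probe sets are not independent replicates. Without replicate 1, 2 or 3 of every group, r was 0.79, 0.77 and 0.81. Of the calls, 736 were higher in both lines, against 70.7 for independent lists, 279 were lower in both, against 21.8, and 0 went opposite ways. Both comparisons used the shared spread of all arrays, so their calls are not independent.

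**Figure D1:**
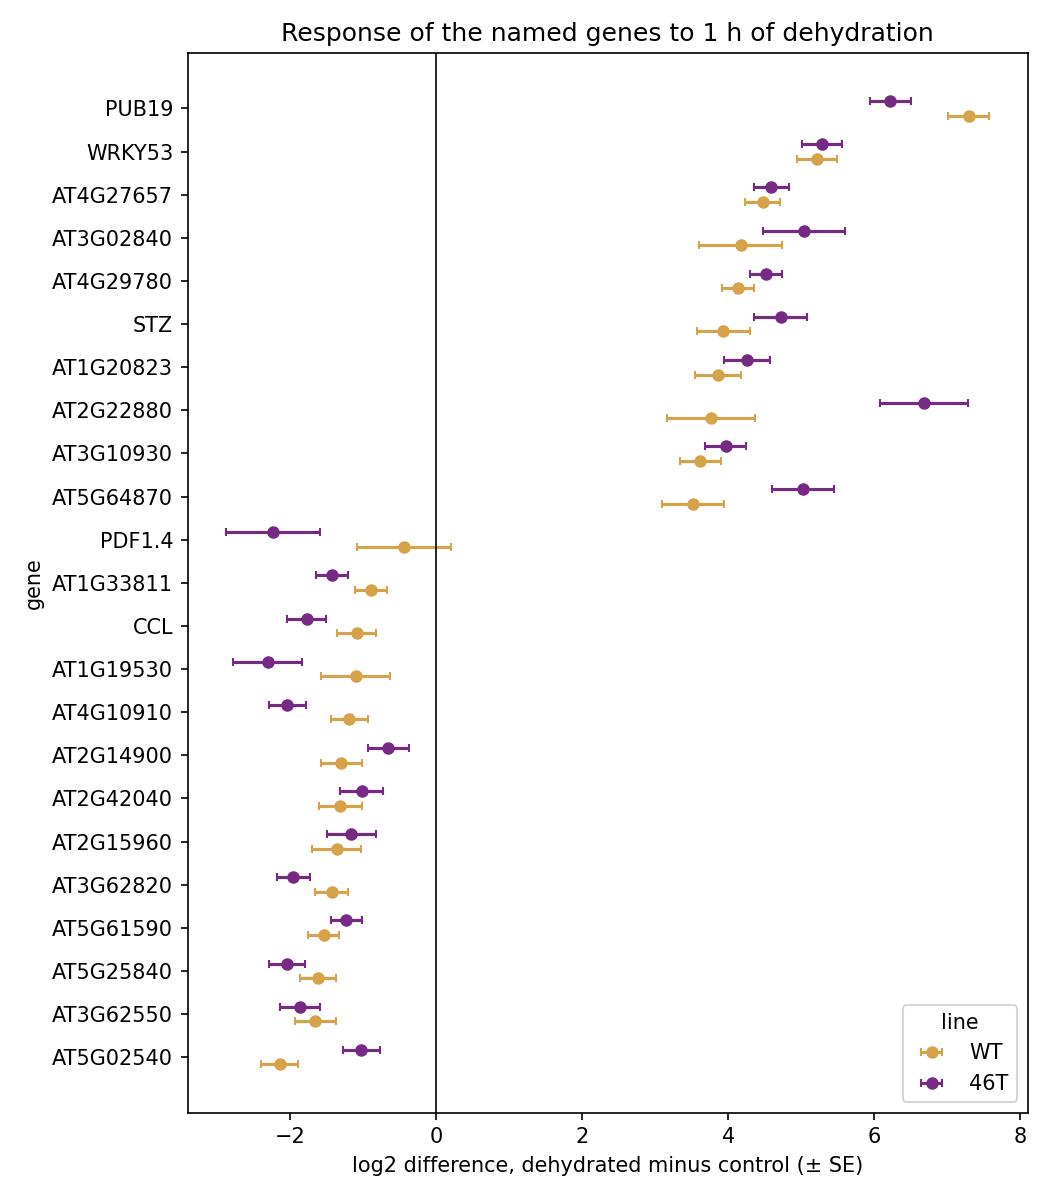
Log2 difference between dehydrated and control seedlings (horizontal axis, with SE) for the genes with the largest rises and falls in either line (vertical axis), in WT and in 46T, from 3 arrays per group. PUB19 rose by 7.29 in WT and 6.22 in 46T, and WRKY53 by 5.21 and 5.28.

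The next comparison set 46T against WT in control seedlings. QQS, a gene known for an effect on starch content, was higher in 46T, at 9.26 ± 0.28 against 6.58 ± 0.60 in WT (SD, n = 3), a log2 difference of 2.68 ± 0.28 (SE; 6.42-fold; limma adjusted p = 9.9e-04). AT1G52000 (2.37 ± 0.39), AT5G39020 (1.68 ± 0.18), AT1G10340 (1.61 ± 0.23), AT2G43530 (1.58 ± 0.31), AT2G25510, AT2G39210 (1.27 ± 0.14) and AT1G14780 (1.24 ± 0.24) were also higher. Lower in 46T were AT3G45160 (-1.54 ± 0.26), the organ growth gene ARL (-1.35 ± 0.26), IAGLU, a glucosyltransferase acting on indole-3-acetic acid (-1.15 ± 0.22), and AT1G73120 (-1.14 ± 0.20). Of 17 alternatives, AT1G14780 lost its call in 13, AT2G43530 in 12, ARL in 10, IAGLU in 8, AT3G45160 and AT1G73120 in 5, AT1G52000 and AT1G10340 in 4, AT2G25510 in 3, AT2G39210 in 1, and QQS and AT5G39020 in 0. Leaving out 46T control replicate 2 or 3 ended the calls of all of these but QQS, AT5G39020 and AT2G39210. Leaving out 46T control replicate 1 ended those of AT1G14780, AT2G43530, ARL, IAGLU, AT3G45160, AT1G73120 and AT1G52000. Leaving out WT control replicate 1 ended those of ARL, IAGLU and AT1G14780, and WT control replicate 3 those of AT2G43530 and AT1G14780.

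QQS was 1 of 3 tested starch genes and the only one of the 24 list genes to pass; adjusted over the list alone, 1 rose and 0 fell. All the tested auxin and growth genes failed the test singly, and their median was -0.34 (camera adjusted p = 0.0115; p = 0.166 with an estimated correlation), a call lost without WT control replicate 3 (adjusted p = 0.0655) or 46T control replicate 2 (adjusted p = 0.0525). By symbol family, the tubulin genes TUB (median -0.30), the expansin genes EXPA (-0.40), RALFL (-0.40), CML (-0.44) and NET (1.44) passed camera at the preset correlation, with no member called. None of the 33 families passed with an estimated correlation, the smallest adjusted p among these 5 being 0.423. Neither the auxin and growth list nor any of these 5 families passed with fry. The camera p of the list had no other list to be adjusted over, while those of the families were adjusted over 33. Without WT control replicate 2, the medians of RALFL and NET were -0.61 and 2.27. Without WT control replicate 1, the medians of RALFL, CML and NET were -0.08, -0.20 and 0.39, and of these 5 only TUB still passed. EXPA, CML and NET also lost their calls without 46T control replicate 2, and NET without 46T control replicate 3.

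In control seedlings 52 probe sets were called, 38 higher and 14 lower in 46T; after quantile normalization the split was 39 to 33, and after median centring 40 to 41. The count was 1640 without WT control replicate 2, 28, 13 and 14 without 46T control replicates 1, 2 and 3, 32 under the stricter filter, 14 in a fit of these groups alone and 2926 with array weights. The level of the poly-A labelling controls, RNAs added before labelling, also differed between the lines, at 8.36 ± 0.33 in WT and 7.85 ± 0.08 in 46T (log2, SD, n = 6 arrays per line; exact permutation within condition, two-sided p = 0.015), and with it in the model 33 probe sets were called.

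The lines were also compared after dehydration. AT3G48650 was higher in 46T by 4.38 ± 0.48 (limma adjusted p = 7.1e-04; 3.52 with the pseudocount), and QQS by 2.95 ± 0.28 (7.74-fold; adjusted p = 1.5e-04), at 8.88 ± 0.24 against 5.92 ± 0.28 (SD, n = 3; limma). AT1G10340 (1.84 ± 0.23), AT5G25440 (1.59 ± 0.20), AT2G24600 (1.24 ± 0.16) and the protein kinase gene PTI1-4 (0.80 ± 0.13) were higher as well, though PTI1-4 lost its call in 8 of 17 alternatives, among them leaving out any array of this comparison. QQS was again the only list gene to pass of 24, and 1 rose and 0 fell with p adjusted over the list alone. The median of the auxin and growth list was 0.13 (camera adjusted p = 0.445), or 0.28 without 46T dehydrated replicate 1 (adjusted p = 0.00678) and -0.03 without 46T dehydrated replicate 3. The families that passed at the preset correlation, plastid-encoded, NAD, UGT and VPS, had adjusted p-values of 0.753, 0.682, 0.189 and 0.753 with an estimated correlation. WRKY53 was at 10.57 ± 0.10 in WT and 10.68 ± 0.38 in 46T.

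After dehydration 22 probe sets were called, all of them higher in 46T, and 20 differed at least 2-fold. The count was 13 without WT dehydrated replicate 3, 14 and 13 without 46T dehydrated replicates 1 and 2, 176 (159 higher, 17 lower) when WT control replicate 1 was left out of the shared spread, 36 after quantile normalization and also with the floor, 43 with the pseudocount, 206 in a fit of these groups alone (191 higher, 15 lower) and 432 with array weights (351 higher, 81 lower).

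The line differences in control and in dehydrated seedlings, which share no arrays, correlated with r = 0.64 and rho = 0.58 across probe sets. Of the calls, 14 were higher in both conditions, against 0.0577 for independent lists, and 0 were lower in both or opposite. Of these, 6 probe sets name 1 gene: QQS, AT1G10340, AT3G48650 and, outside the rule for named genes, AT2G15042 (2.94 ± 0.46 in control and 4.56 ± 0.46 in dehydrated seedlings; 1.76 and 2.41 with the pseudocount), AT5G25470 (2.47 ± 0.33 in both) and AT1G74440 (1.44 ± 0.21 and 1.63 ± 0.21). In control seedlings AT2G15042, AT1G10340 and AT1G74440 lost their calls without 46T control replicate 2 or 3, and AT3G48650 without 46T control replicate 2. The correlation was 0.45 without replicate 1 of every group and 0.50 without WT control replicate 1 alone. Both comparisons used the shared spread of all arrays, so their calls are not independent. The poly-A level also differed between the lines alike in control and dehydrated seedlings (-0.51 and -0.50, 46T minus WT). Neither the overlap nor the correlation can therefore tell a line effect from that array difference.

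**Figure D2:**
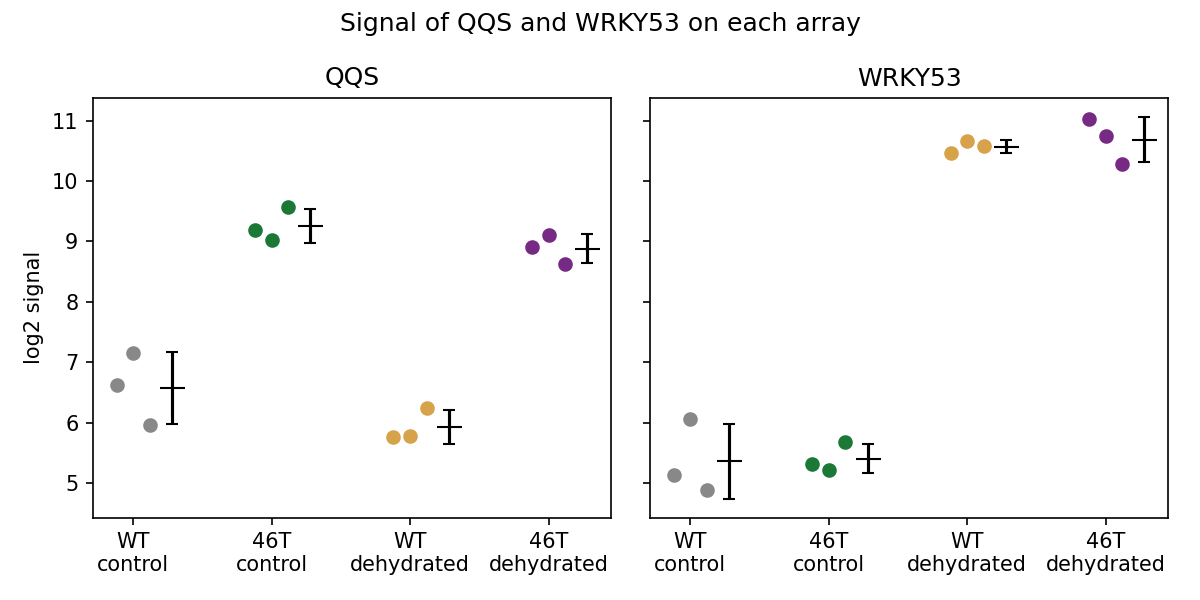
Log2 signal (vertical axis) of QQS and WRKY53 on each array (points) in the 4 groups (horizontal axis), with the mean and SD of each group in black (n = 3). QQS was at 9.26 and 8.88 in the 46T groups and at 6.58 and 5.92 in the WT groups, and WRKY53 was at 10.57 and 10.68 in the dehydrated groups and at 5.36 and 5.40 in the controls.

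The last comparison asked whether the response to dehydration differed between the lines. No probe set was called by limma (smallest adjusted p = 1.00), and 291 had an unadjusted p under 0.05, against 725 by chance. Array weights and the poly-A term each gave 1 call. The 5 named genes with the smallest p, none of which passed, were AT2G46600 (0.76 ± 0.18), CML38 (1.87 ± 0.44), AT2G24600 (0.93 ± 0.23), AT1G69840 (0.83 ± 0.21) and TBL38 (0.75 ± 0.21), each with a more positive response in 46T. As sets, the CML genes (median 0.58, camera adjusted p = 5.9e-06; adjusted p = 0.191 with an estimated correlation), the auxin and growth list (0.41, adjusted p = 4.5e-04; p = 0.0669 with an estimated correlation) and the LSM genes (0.31, adjusted p = 0.0238; adjusted p = 0.695 with an estimated correlation) responded more positively in 46T. The plastid-encoded genes responded more negatively (-0.26, adjusted p = 5.9e-06; adjusted p = 0.695 with an estimated correlation). No member of these sets passed singly, and none of these sets passed with fry. The camera p of the list had no other list to be adjusted over, while those of the families were adjusted over 33. The LSM call was lost without WT control replicate 1 (median 0.07), 46T control replicate 2, WT dehydrated replicate 2 or 3, or 46T dehydrated replicate 2, and the plastid-encoded call without WT control replicate 2 (median -0.09; -0.47 without WT control replicate 3). The median of the auxin and growth list was 0.71 without 46T control replicate 3. Adjusted over the list alone, 1 of the 24 list genes had a more positive response in 46T. At this number of arrays, 35% of simulated 2-fold interactions were recovered, for probe sets at or above the median signal with an equal spread on all arrays.

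**Figure D3:**
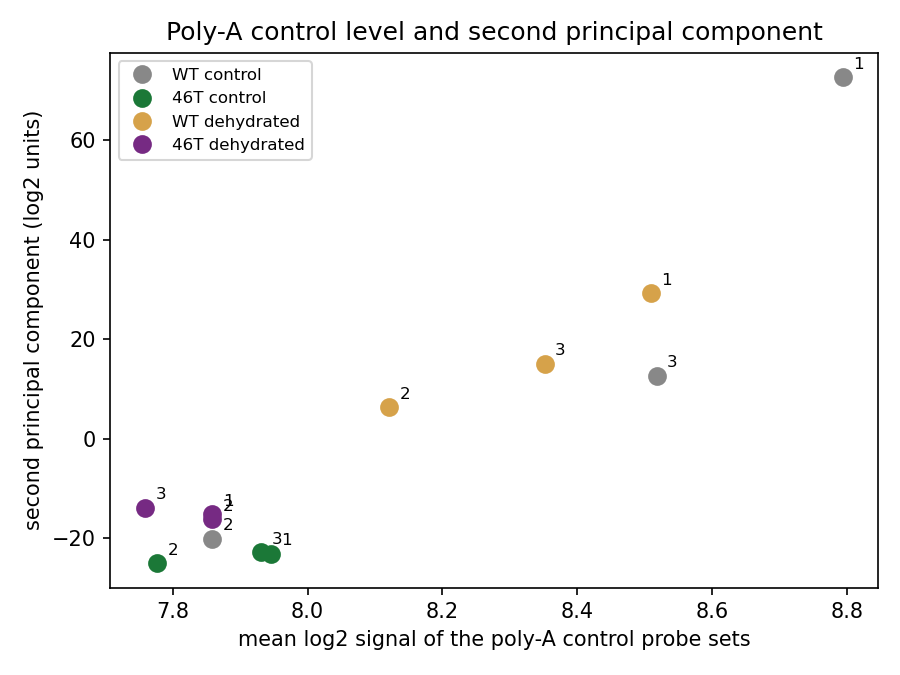
Second principal component (vertical axis, log2 units) against the mean log2 signal of the poly-A control probe sets (horizontal axis) for the 12 arrays, coloured by group and numbered by replicate. WT control replicate 1 lies at 72.7, and WT control replicate 2, at -20.1 and 7.86, lies among the 46T arrays.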

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

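The tests on the poly-A controls and with an array left out were chosen after these results were seen. The response to dehydration differed between the lines, by camera at its preset correlation, in 4 gene sets: the CML genes (adjusted p = 5.9e-06), the plastid-encoded genes (5.9e-06), the LSM genes (0.0238) and the auxin and growth list (4.5e-04). With an estimated correlation their adjusted p-values were 0.191, 0.695, 0.695 and 0.0669, and no member passed singly. The estimated correlations were 0.17, 0.28, 0.63 and 0.46 in the same order, against the preset 0.01. None of the 4 sets passed with fry. The camera p of the auxin and growth list equals its unadjusted p, while those of the families were adjusted over 33.

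The interaction was positive for all 7 CML genes, all 6 LSM genes and all 5 tested auxin and growth genes, and for 15 of the 67 plastid-encoded genes. Without WT control replicate 1 the median of the LSM genes was 0.07 (adjusted p = 0.831), and the LSM call was also lost without 46T control replicate 2, WT dehydrated replicates 2 or 3, or 46T dehydrated replicate 2. The plastid-encoded call was lost without WT control replicate 2 (median -0.09, adjusted p = 0.679). The CML genes and the auxin and growth list passed with any 1 array left out at the preset correlation, but not with an estimated one (adjusted p = 0.191 and 0.0669). A labelling difference cannot be told apart from an effect of the line in any of these sets. With the poly-A level as a term the ratio of the median to that without it was 0.999 for CML, 1.01 for plastid-encoded, 0.992 for LSM and 1.00 for auxin and growth genes. That test is void, because the poly-A level differed between the lines by -0.51 in control and -0.50 in dehydrated seedlings, and the term can then hardly move an interaction.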

How the results depend on the processing

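No named gene followed through the alternatives turned. The camera direction of the auxin and growth list turned in 2 comparisons where it had not passed, without 46T dehydrated replicate 3: dehydration in 46T (median -0.14, adjusted p = 0.946) and the lines in dehydrated seedlings (median -0.033, adjusted p = 0.553). Its medians with 1 array left out ranged from -0.27 (without 46T dehydrated replicate 2) to 0.37 (without 46T dehydrated replicate 1) in the former and from -0.033 to 0.28 (without 46T dehydrated replicate 1) in the latter. The cause was not tested. Lists and families were run under 5 other settings and with each compared array left out, the latter added after seeing the data; families that did not pass were not followed, except the CML genes in WT. Over called named genes, 444 results with 1 array left out and 915 under other settings kept their side of the threshold, and 78 and 53 lost it. Named genes not called gained a call in 2 results with 1 array left out and 7 under other settings. Called families lost theirs in 37 results under other settings and kept it in 68, and with an array left out in 22 and 131; the called list results lost theirs in 4 and kept it in 6, and with an array left out in 2 and 16. Array weights gave 3469 calls for dehydration in WT, 3770 in 46T, 2926 and 432 for the lines in control and dehydrated seedlings, 1 for the interaction and 3752 for the lines averaged over both conditions. A fit of only the groups compared, each with its own spread estimate and fewer arrays, gave 751, 3079, 14 and 206 for the first 4. A 2-fold minimum left 701 and 733 for dehydration by construction. For the lines in control seedlings, median centring gave 81 and the stricter filter 32; in dehydrated seedlings quantile normalization and the floor each gave 36 and the pseudocount 43; averaged, the stricter filter gave 144. The poly-A control level as a term gave 2265 for dehydration in 46T, 33 for the lines in control seedlings, 1 for the interaction and 42 for the averaged lines. The stricter filter raised the correlation of the dehydration responses to 0.90. Apart from those set by construction, the cause was not tested. With 1 array left out, counts ranged from 833 to 2372 (dehydration in WT), 772 to 2382 (46T), 13 to 1640 (lines, control), 13 to 176 (lines, dehydrated) and 0 to 0 (interaction), and the averaged lines gave 420 without WT control replicate 1. Without WT control replicate 1 the correlations were 0.84 and 0.50, and without 1 replicate number in every group, which leaves out 4 arrays, they ranged from 0.77 to 0.81 and from 0.45 to 0.64.

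The labels do not say that a replicate number marks arrays handled together, so the arrays were not treated as paired. Deviations from the group means of arrays sharing a number correlated with r from -0.12 to 0.35 (median 0.03; highest 0.14 between other numbers), and 8 of 12 arrays correlated best with one of their own number, a hint from the data that some numbers share something. With the replicate block the counts were 1778, 1592, 65, 24 and 0 for the 5 comparisons and 423 for the averaged lines. The correlations (0.85 and 0.64) cannot move with it, since a block leaves differences of group means in a balanced design as they are. Members of the fixed lists that did not pass are given as counts and were not followed through the alternatives, except in the auxin and growth list; in an earlier run some of their small differences changed sign. Signals near the floor limit the folds of weakly expressed genes.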

Other observations

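The contrast averaged over both conditions and the tests on the poly-A controls, on WT control replicates 1 and 2 and on chromosomal placement were chosen after seeing the data. For placement and for WT control replicate 2 as a 46T sample, the bounds too were written after the values were seen. Averaged over control and dehydrated seedlings, 46T differed from WT in 239 probe sets, 165 higher and 74 lower, or 183 and 146 after quantile normalization. With the poly-A level as a term 42 were called, and without WT control replicate 1, 420. QQS was higher by 2.82 ± 0.20 (SE, 6 arrays per line, limma adjusted p = 4.3e-06), and CHI, annotated as a chitinase gene and picked after its value was seen, by 1.76 ± 0.22 (limma adjusted p = 6.9e-04). Under 10 alternatives the difference of CHI lay between 1.48 and 1.88, and its call was lost only with the poly-A level as a term (adjusted p = 0.0511). None of the 33 families passed in this contrast with an estimated correlation (smallest adjusted p = 0.435).

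Other groupings of the arrays were also fitted. For each comparison of 3 against 3 arrays only 10 splits exist, too few for a share under 0.05; only 1 split, the real one, gave as many calls in each. The highest other split gave 0 calls against 1680 for dehydration in WT, 0 against 1476 in 46T, 0 against 52 for the lines in control seedlings and 7 against 22 in dehydrated ones. For the averaged line difference, 1 of 100 splits, the real one, gave as many as 239 calls and the highest other gave 2, so an accidental division of the arrays is argued against. For the interaction, with 0 calls, all 100 splits give as many by construction, so this count says nothing about chance; the highest other gave 239 because exchanging the lines in 1 condition turns the interaction into the averaged line difference.

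The probe sets called between the lines stand beside a difference between whole arrays, seen in the poly-A controls and the second principal component. With the level of these controls as a term, the median ratio of the difference to that without it was 0.908 over the 74 differences called. That ratio cannot decide whether a labelling difference is the whole cause. Calls made without the term favour probe sets that vary little with the poly-A level within groups, which the term can hardly move. With the term, 21 of the 52 calls in control seedlings stayed, 15 of the 22 in dehydrated ones and 33 of the 239 for the averaged lines. QQS remained higher in control seedlings, by 2.41 ± 0.33 (SE, limma adjusted p = 0.00331). For the called probe sets as a group, a labelling difference stays open. WT control replicate 2 shares the poly-A level of the 46T arrays. Over the 22 probe sets called in dehydrated seedlings it lay a median of 0.185 of the way from the other WT control arrays to 46T (quartiles -0.13 to 0.29), with 21 below the midpoint. The median is under the bound of 0.2, but by less than the median absolute deviation over the square root of the number of probe sets. The array difference thus cannot be told apart from an effect of the line. An effect of the line stays a hypothesis, and gene length is not weighed here.

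WT control replicate 1 stood apart on the second principal component, for a reason not settled here. Its QQS level of 6.62 lay below the midpoint of 7.91 between the lines. Its WRKY53 level of 5.13 lay below the midpoint of 8.02 between control and dehydrated WT seedlings. These levels argue only weakly against a mislabelled 46T or dehydrated sample, since both genes were picked with this array counted as WT control. Both were also called where this array was not compared, QQS between the dehydrated lines and WRKY53 for dehydration in 46T. The shared spread in those calls still includes this array. On the first principal component, which used no group labels, WT control replicate 1 lay at -38.5. The other control arrays lay between -36.5 and -32.1, and the dehydrated arrays between 22.8 and 46.9. These positions argue against a mislabelled dehydrated sample, but say nothing about a mislabelled 46T control. For WT control replicate 2, which lies among the 46T arrays, the QQS level of 7.16 lies below the midpoint of 7.77. That too argues only weakly against a 46T sample, for the same reason. No biological explanation was tested for either array.

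Of the 32 named genes called between the lines, 2 pairs lay within 10 annotated genes of each other (AT5G25470 with AT5G25440, and AT2G43530 with CHI; assembly TAIR10.1), and 3.6% of 10000 random draws of as many tested genes gave as many pairs. The second pair rests on AT2G43530, whose call was lost in 12 of 17 alternatives.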
